A study of Mus musculus with 6 samples.

How the data were processed

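The series holds 6 RNA-seq libraries of mouse (C57BL/6) bone marrow cells sorted for Kit, 3 from WT mice and 3 from Ints11 KO littermates. Per the labels' protocols, total RNA of individual mice was isolated with TRIzol, and libraries were made with a strand-specific Illumina TruSeq messenger RNA kit and sequenced as paired reads of 75 bp. The deposited table gives raw read counts per gene symbol, 1 column per library, with no normalization by the authors. The submitters' processing notes list FastQC, Trimmomatic, STAR and HTSeq without versions, and the genome build mm10. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. If reads with several best positions were dropped, as is usual in such counting, genes with near-identical copies (histones, ribosomal proteins, small nuclear RNAs, globins) are undercounted. Whether the WT littermates carried the Mx1-Cre transgene is not given in the sources used here.

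The table lists 24062 symbols, of which 19863 had at least 1 count. No column belonged to other samples. A spreadsheet had turned 12 symbols into dates, 10 of which were tested under those names. The 6 adult globin genes are listed at 0 in all libraries, so globin levels were not assessed, and no mitochondrially encoded genes are listed. Symbols were matched to GENCODE M21 on GRCm38 (the assembly of mm10), 22697 directly and 903 through RefSeq synonyms, with 462 unmatched. Positions are 1-based.

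Groups came from the genotype labels. Library pairs were compared by the chi-square statistic of their counts, which was between 61.5 and 1186 per degree of freedom, so no library was a second deposit of another. Xist and Y-linked counts showed that WT_341, KO_339 and KO_340 came from males and WT_343, WT_344 and KO_345 from females. The labels share no replicate numbers between genotypes and name no batch.

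Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with its defaults (minimum count 10, minimum total count 15), TMM factors, glmQLFit with robust estimation and glmQLFTest for genotype, with Benjamini-Hochberg adjustment over the 15742 genes that passed the filter and a threshold of 0.05. Levels are TMM-scaled CPM given as mean ± SD of 3 libraries, and log2 changes carry the standard error of the fit. Totals of 124074531 to 166860739 counts put the counting error of genes with many reads far below the spread between mice. Library totals and shares were compared by exact two-sided permutation tests over the 20 assignments of 3 and 3 libraries, which cannot go below p = 0.10; 9 such measures were tested, and the smallest value adjusted over them was 0.15. Principal components of log2 CPM put 58.8% of the variance on the component that separated the genotypes and 23.1% on the next, on which WT_341 (59.9) lay apart from WT_343 (-29.6) and WT_344 (-16.5).

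The design, the alternatives, the 27 gene lists and the rule for named genes were fixed before the data were examined. The named genes are Ints11, the 10 genes with the largest rise and the 10 with the largest drop among those past the threshold with a mean of at least 5 CPM and groups that do not overlap (without unnamed gene models, pseudogenes marked -ps, and sex-linked marker genes), and for each list up to 4 tested members with the smallest adjusted p; 1 of these genes is not reported here. Kit, the neighbours of small nuclear RNA genes, Clasp1 and 2900060B14Rik were chosen after their values were seen. The lists cover Integrator subunits, messenger RNA 3' end cleavage and histone messenger RNA processing factors, PRC2 subunits, Hox genes, inhibitors of cyclin-dependent kinases, p53 targets, DNA replication and G1/S genes, G2/M and mitosis genes, replication-dependent histones, spliceosomal small nuclear RNAs, BCL2 family and caspases, interferon-stimulated genes, immediate early genes, NF-kB and inflammatory genes, unfolded protein and integrated stress response genes, and cytosolic ribosomal proteins. Cell type lists cover haematopoietic stem cells, granulocyte-macrophage progenitors and granules, monocytes and dendritic cells, erythroid cells, megakaryocytes, mast cells with basophils and eosinophils, lymphoid progenitors and B cells, mature neutrophils, T and NK cells, macrophages, and stromal and endothelial cells. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), at the preset correlation of 0.01 and with an estimated one, and with fry. Members past the threshold were counted over all genes tested and adjusted over the list alone. A further 6 lists (sterol biosynthesis, mitochondrial ribosomal proteins, aminoacyl-tRNA synthetases, ribosome biogenesis, glycolysis, Schlafen genes) were chosen after the data were seen.

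The gene test was tried on simulated counts for this comparison (15587 genes). It recovered 1 of 50 genes changed 1.25-fold, 6 of 49 changed 1.5-fold, 24 of 50 changed 2-fold and 31 of 50 changed 4-fold. Of its 72 calls 10 were false (13.9%), while 4.49% of unchanged genes had an unadjusted p under 0.05. Far fewer genes were changed in the simulation than were called in the data, so these rates need not hold for the real comparison. In simulated data with independent genes, camera and fry called 0 of 30 lists of unchanged genes and called a list raised 1.4-fold; correlation between genes was not simulated.

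Alternatives were RLE and upper-quartile factors, library totals only, no low-count filter and 2 other filters, DESeq2 1.42.0, limma-voom with and without sample quality weights, edgeR without robust estimation, each library left out in turn, the 10 most counted genes left out, sex as a covariate, and the fit without Xist and Y-linked genes. The level of the mature neutrophil list as a covariate was added after the data were seen. Copies of small nuclear RNAs were classed by an edit distance of at most 5% to the named mouse genes (edlib), and Fisher's exact and permutation tests used scipy 1.17.1.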

Results

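Messenger RNA was profiled in Kit-positive bone marrow cells, a sorted population rich in blood stem and progenitor cells that the series description also calls lineage-negative. The cells came from 3 wild-type (WT) mice and 3 littermates with floxed Ints11 alleles and the Mx1-Cre transgene (Ints11 KO), with 1 mouse per library. Cre was induced with poly(I:C), an RNA mimic that triggers interferon, and cells were collected 4 days later. The time of 4 days after poly(I:C) is given for all 6 libraries, WT included. INTS11 is the catalytic endonuclease of Integrator, the complex that cleaves the 3' ends of small nuclear RNAs and ends transcription close to promoters. The comparison asks which transcripts differ between progenitors of the 2 genotypes. Libraries are named here by genotype and mouse number. Total counts were 124074531 in WT_341, 166860739 in WT_343 and 151923916 in WT_344, and 142983542 in KO_339, 127323153 in KO_340 and 127011537 in KO_345. The totals of the genotypes were not distinguishable (n = 3 each, exact two-sided permutation test, p = 0.40, smallest possible p = 0.10). The 10 most counted genes took 7.56 ± 1.42% of counts in WT and 9.71 ± 0.0942% in KO libraries (n = 3 each, same test, exact p = 0.10).

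Ints11, listed under its older symbol Cpsf3l, fell in the KO libraries from 81.7 ± 9.59 to 60.96 ± 3.08 CPM (CPM are counts relative to the TMM-scaled library total; SD, n = 3 each). Its log2 change was -0.42 ± 0.10 (SE), with an adjusted p of 0.0174 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Single WT libraries held 73.8, 92.3 and 78.9 CPM and single KO libraries 64.3, 58.3 and 60.2 CPM, so all 3 KO libraries lay below all 3 WT libraries. The gene spans positions 155869546 to 155889103 on the forward strand of chromosome 4 (GRCm38, the assembly that mm10 names). The floxed exons are not given in the sources used here and reads over all other exons also count for the gene, so this level checks the genotype labels only in part. The call was lost without KO_340 (log2 change -0.36, adjusted p = 0.0557), without KO_345 (-0.38, adjusted p = 0.0541) and with the level of the mature neutrophil list as a covariate (-0.22, adjusted p = 0.298), and the adjusted p ranged from 0.00127 to 0.298 over 20 alternatives.

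Slfn14, which encodes a ribosome-associated endoribonuclease of the Schlafen family, showed the largest rise of the genes that met the rule for named genes, from 0.245 ± 0.117 to 60.5 ± 5.95 CPM, a fitted 243-fold. Eda2r, a receptor of the tumour necrosis factor receptor family, rose 27.1-fold to 11.1 ± 1.59 CPM, and Phlda3, an inhibitor of Akt signalling, rose 12.7-fold to 12.9 ± 0.821 CPM. Clec12b, an inhibitory C-type lectin receptor, rose 23.7-fold and Clec1b, the platelet receptor CLEC-2, rose 10.8-fold, and both genes lie on chromosome 6. Ceacam19 rose 19.4-fold, the adenylate kinase gene Ak1 11.7-fold and the collagen gene Col1a1 10.1-fold, the last with a wide spread between KO libraries (30.1, 8.79 and 17.6 CPM). Tex14, a gene of germ cell bridges, rose 16.7-fold to 13.7 ± 2.17 CPM, and Rdm1, which encodes a protein with a RAD52 motif, rose 8.71-fold to 75.4 ± 14.04 CPM. All 10 had adjusted p-values between 0.000124 and 0.00382 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of these, Col1a1 (log2 change from 3.34 to 2.60) no longer passed with the mature neutrophil covariate.

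Several of these genes lie beside small nuclear RNA genes in the annotation. Tex14 (chromosome 11, 87405065 to 87555823, forward strand) holds the U1 gene Rnu1a1 (87422867 to 87423030) and the U1 copy Gm22068 (87426716 to 87426879) on its own strand, both outside its annotated exons. Rdm1 (chromosome 11, 101627195 to 101636100, forward strand) holds the U2 copy Gm23849 (101627366 to 101627556), also outside its annotated exons. Slfn14 (chromosome 11, 83275110 to 83286726, reverse strand) lies 3422 bp from the U2 copy Gm23444 on the opposite strand. The strand setting used in counting is not given in the sources used here, so reads from overlapping transcripts cannot be assigned to a strand with certainty.

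Among the genes that fell and met the same rule, Apba1, which encodes a synaptic adaptor protein, showed the largest drop, from 16.3 ± 2.44 to 2.16 ± 1.2 CPM (log2 change -2.91 ± 0.37, SE). Ccr2, the chemokine receptor of monocytes, fell from 92.9 ± 9.26 to 25.2 ± 0.538 CPM and F13a1, the coagulation factor XIII A chain, from 206 ± 30.4 to 62.1 ± 25.8 CPM. The receptor tyrosine kinase gene Met fell from 49.7 ± 2.18 to 14.9 ± 4.47 CPM, the ErbB ligand gene Nrg1 from 19.7 ± 4.95 to 4.73 ± 1.12 CPM and the collagen receptor subunit gene Itga1 from 10.7 ± 1.97 to 2.64 ± 0.655 CPM. Fut10 (log2 change -1.75) and Bphl (-1.67) also fell. Tmem56 (-2.14) and Gpt2 (-2.11), the second a mitochondrial alanine aminotransferase, fell from WT levels that 1 library set: 19.4 CPM in WT_341 against 4.16 and 4.602 CPM for Tmem56, and 22.7 CPM in WT_343 against 6.72 and 7.29 CPM for Gpt2. Both calls were lost when any single KO library was left out, and Tmem56 also with no low-count filter and with limma-voom. With the mature neutrophil covariate Gpt2 (log2 change from -2.11 to -0.70), Apba1 (from -2.91 to -2.74), Met (from -1.74 to -1.55) and F13a1 (from -1.73 to -1.26) no longer passed. The adjusted p-values of the 10 genes lay between 0.000218 and 0.0291 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

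**Figure D1:**
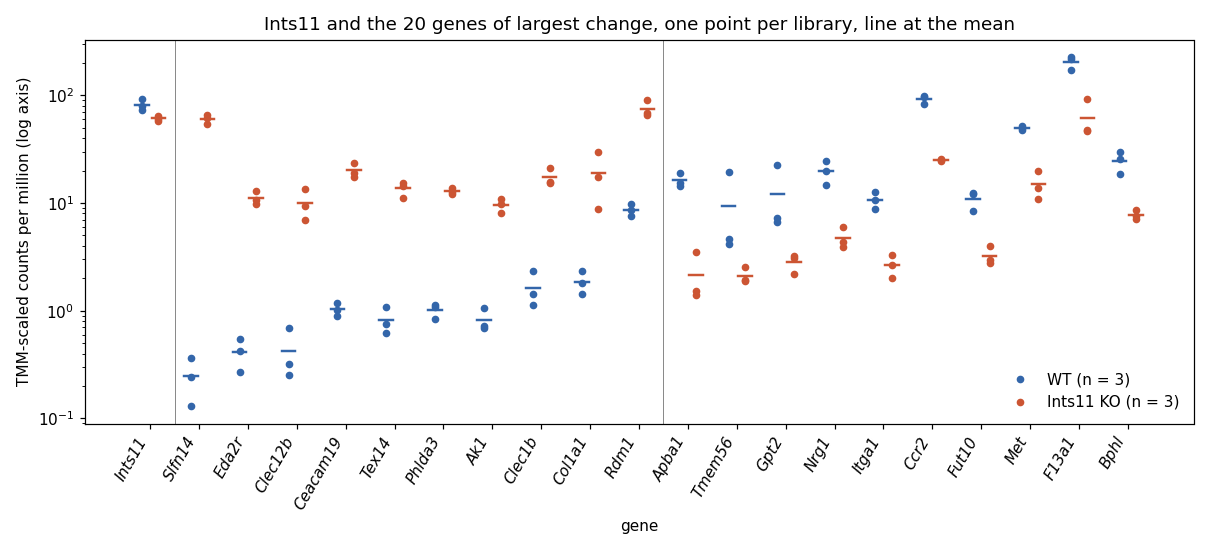
TMM-scaled CPM (log axis) of Ints11 and of the 10 genes with the largest rise and the 10 with the largest drop, 1 point per library (3 WT, 3 Ints11 KO), with a line at each group mean. Slfn14 lies between 0.1298 and 0.365 CPM in WT and between 54.1 and 65.9 CPM in KO libraries.

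In all, 5659 of 15742 tested genes changed (35.9%), 2520 higher and 3139 lower in KO libraries, at an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of the 1536 that changed at least 2-fold, 1359 were higher and 177 lower. The groups did not overlap for 8492 tested genes (53.9%, against 10% by chance). Scaling moved the balance of directions: 44.5% of calls were higher with TMM, 64.2% with upper-quartile factors and 58.8% with library totals only, as the median log2 change of all tested genes went from 0.01 to 0.15 and 0.11. Leaving out single libraries gave 2302 calls without KO_339, 2966 without KO_345, 3270 without WT_344 and 3316 without KO_340, and 7879 without WT_341, and left 848 genes changed at least 2-fold without KO_339 and 937 without KO_345. With the level of the mature neutrophil list as a covariate, chosen after the data were seen, 876 genes passed, of which 767 were among the 5659, and all 767 kept their direction. The median SE of the log2 change over the tested genes was 0.149 without and 0.188 with that covariate, so a lost call can go with an equal or larger change. The level of the neutrophil list was higher in every KO library (mean log2 CPM 7.865 to 8.31) than in every WT library (6.23 to 7.61). The covariate therefore overlaps with genotype and can take up part of a genotype effect. Lost calls do not show that neutrophils account for a change.

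The 26 gene lists with at least 5 tested members were compared with all other genes by camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. It called 19 lists, 12 higher and 7 lower in KO libraries. None was called with an estimated correlation, and fry, which tests each list by itself, called 13. The other splits of the same 6 libraries gave between 9 and 22 camera calls. Of all tested protein-coding genes 16.1% were called higher and 21.5% lower, so a member count near these shares does not set a list apart. Near them were the lower interferon-stimulated (9 of 40) and erythroid genes (6 of 30). So were the higher NF-kB (4 of 26) and lymphoid genes (4 of 23). Camera did not match lists on expression level, and direction differed with that level. Of all calls 2520 were higher and 3139 lower. Among calls with a mean of at least 5 CPM and groups that do not overlap, 1032 were higher and 2942 lower (without unnamed gene models, pseudogenes and sex-linked genes). A list of strongly or weakly expressed genes can therefore differ from all other genes partly through its level, which was not tested. With the mature neutrophil level as a covariate, 19 p53 targets and 6 megakaryocyte genes were higher and 10 replication genes lower, with median log2 changes of 1.04, 1.64 and -0.31. In the same fit 1 stem cell gene was higher (median 0.55, against 0.81 without the covariate), and 0 ribosomal protein genes (-0.16 against -0.42) and 0 messenger RNA 3' end factors (-0.15 against -0.26) were lower. Stromal, T and NK cell and Hox genes had 0, 2 and 0 higher calls, while their medians went from 0.83, 1.16 and 0.34 to 1.53, 1.31 and 0.60.

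Of 31 tested targets of p53, 20 rose and 0 fell (21 and 0 adjusted over the list alone), with a median log2 change of 1.01 (camera adjusted p = 5.63e-09, adjusted p = 0.0718 with an estimated correlation). Besides Eda2r and Phlda3, Zmat3, an RNA-binding growth inhibitor, rose 6.69-fold to 26.97 ± 6.78 CPM and Psrc1, a spindle protein gene, rose 2.58-fold to 29.99 ± 0.917 CPM. The list shares 8 members with other lists. Among the inhibitors of cyclin-dependent kinases, 4 of 7 rose and 0 fell (6 and 0 adjusted over the list alone; camera adjusted p = 0.0116, adjusted p = 0.482 with an estimated correlation). Cdkn1a, the p53-regulated inhibitor p21, rose 5.698-fold from 11.8 ± 2.73 to 67.5 ± 10.7 CPM. Cdkn1b rose by 0.43 and Cdkn2d by 0.54 on the log2 scale, and Cdkn2b by 1.96 at only 0.129 ± 0.0187 CPM in KO libraries. The calls of Cdkn1b, Cdkn2b and Cdkn2d were lost when any single KO library was left out, Cdkn1b and Cdkn2b also without WT_343 and Cdkn1b and Cdkn2d also without WT_344, and Cdkn2b also with DESeq2. With the neutrophil covariate the inhibitors were 1 higher and 1 lower (median 0.12 against 0.54). Cdkn1b (log2 change from 0.43 to 0.12), Cdkn2d (from 0.54 to 0.09) and Cdkn2b (from 1.96 to 2.33) no longer passed. The BCL2 family and caspases moved both ways, with 7 higher and 5 lower of 29 (7 and 5 adjusted over the list alone), and camera made no call (adjusted p = 0.577). Bbc3, which encodes the death activator PUMA, rose 4.32-fold to 14.1 ± 1.37 CPM and Bok, another pro-death family member, rose 3.62-fold, while Casp2 (log2 change -0.48) and the BH3-only gene Bid (-0.63) fell. The BCL2 family and caspases with that covariate were 2 higher and 1 lower (median -0.03 against 0.04). Bok (log2 change from 1.86 to 2.02) and Bid (from -0.63 to -0.41) no longer passed.

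Genes of DNA replication and the G1/S step fell, 26 of 35 with 0 higher (28 and 0 adjusted over the list alone). Their median log2 change was -0.39 (camera adjusted p = 5.38e-09, adjusted p = 0.482 with an estimated correlation). The replicative helicase gene Mcm7 fell from 485 ± 24.7 to 293 ± 6.28 CPM, the origin licensing factor gene Cdc6 from 134 ± 9.61 to 77.8 ± 4.28 CPM, Mcm10 from 122 ± 10.8 to 76.5 ± 1.83 CPM and the thymidine kinase gene Tk1 from 121 ± 2.27 to 77.2 ± 6.53 CPM. Of 32 G2/M and mitosis genes, 12 fell and 0 rose (14 and 0 adjusted over the list alone), with a median of -0.16 (camera adjusted p = 0.00360, adjusted p = 0.626 with an estimated correlation). The spindle checkpoint kinase gene Bub1 (log2 change -0.67), the mitotic cyclin gene Ccnb2 (-0.44), Hmmr (-0.35) and Birc5 (-0.34), which encodes survivin, were among them, and the call of Birc5 was lost without KO_340 or KO_345. Upper-quartile scaling left 3 of these mitosis genes lower with a median of -0.02, and 19 of the 35 replication genes lower with a median of -0.25. G2/M genes with the neutrophil covariate were 0 higher and 2 lower (median -0.21 against -0.16). Birc5 (log2 change from -0.34 to -0.43), Ccnb2 (from -0.44 to -0.52) and Hmmr (from -0.35 to -0.29) no longer passed, and Birc5 was also lost with upper-quartile scaling.

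Of 57 tested replication-dependent histone genes, 5 rose and 2 fell (0 and 0 adjusted over the list alone), with a median log2 change of 0.41 (camera adjusted p = 0.0109, adjusted p = 0.704 with an estimated correlation). Hist1h4i rose 3.88-fold, with 116, 145 and 43.7 CPM in the KO libraries, and Hist1h2bl rose 1.77-fold, while Hist1h1b, a linker histone gene, and Hist2h2bb fell by 0.35 and 0.32 on the log2 scale. Both falls were lost with upper-quartile scaling and with library totals only, under which 10 members rose and 0 fell, and that of Hist1h1b also with a filter of at least 1 CPM in 3 libraries. The call of Hist1h4i was lost without any single library but KO_345, that of Hist1h2bl without WT_341, WT_343, KO_339 or KO_340, and those of Hist1h1b and Hist2h2bb without WT_344 or any KO library. The camera call was lost without WT_341, WT_343 or KO_340 (adjusted p = 0.102, 0.102 and 0.113, in a range from 1.03e-06 to 0.113 over the libraries left out). The members are near-identical copies whose reads can be split or dropped in counting. Most of their messenger RNAs lack poly(A) tails. The libraries were made with a messenger RNA kit, so the counts do not measure total histone messenger RNA. Histone genes with the neutrophil covariate were 0 higher and 1 lower (median 0.51 against 0.41). Hist1h4i (log2 change from 1.96 to 0.91), Hist1h2bl (from 0.82 to 0.70) and Hist2h2bb (from -0.32 to -0.39) no longer passed. Hist1h4i and Hist1h2bl were also lost with no low-count filter, and Hist1h2bl with sex as a covariate.

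Subunits of the Polycomb complex PRC2, which methylates histone H3, fell in 5 of 12 cases with 0 higher (5 and 0 adjusted over the list alone; camera adjusted p = 0.0319, adjusted p = 0.563 with an estimated correlation). Suz12 fell from 318 ± 17.5 to 231 ± 1.34 CPM, and Phf19 (log2 change -0.45), Rbbp7 (-0.49) and Mtf2 (-0.36) also fell. The calls of Rbbp7 and Mtf2 were lost without WT_344 or KO_339, Mtf2 also without KO_345, and upper-quartile scaling left 3 members lower. Of 13 tested Hox genes, 3 rose and 0 fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.0460, adjusted p = 0.482 with an estimated correlation). These were Hoxa10 (2.22-fold), Hoxa6 (2.202-fold) and Hoxa5 (1.91-fold), all with KO means of 3.12 CPM or less. Hoxa4, with a log2 change of 0.70, did not pass (adjusted p = 0.0685, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and passed with upper-quartile factors (0.84), library totals only (0.80) and limma-voom with sample quality weights (0.74). The camera call of the Hox list was lost without WT_341 (adjusted p = 0.0920) or KO_340 (0.0758). The neutrophil covariate left PRC2 subunits at 0 higher and 0 lower (median -0.14 against -0.21). Suz12 (log2 change from -0.47 to -0.35), Phf19 (from -0.45 to -0.34), Rbbp7 (from -0.49 to -0.18), Mtf2 (from -0.36 to -0.15), Hoxa10 (from 1.15 to 1.249), Hoxa6 (from 1.14 to 1.02) and Hoxa5 (from 0.93 to 0.73) no longer passed.

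The list of Integrator subunits moved both ways: 2 of 18 rose and 6, Ints11 included, fell (2 and 7 adjusted over the list alone), and camera made no call (adjusted p = 0.104). Ints7 fell from 144 ± 11.03 to 101 ± 5.34 CPM. Nabp1, counted in the Integrator list, encodes a single-stranded DNA binding protein of the SOSS complex. It rose 3.12-fold from 21.8 ± 9.97 to 68.2 ± 10.9 CPM. Asun, the older symbol of Ints13, was the other member that rose, 1.29-fold, a call that was lost without WT_344. With upper-quartile scaling 4 members of the list rose and 2 fell, and without WT_341 4 rose and 9 fell. Of 23 factors of messenger RNA 3' end cleavage and histone messenger RNA processing, 10 fell and 0 rose (11 and 0 adjusted over the list alone; camera adjusted p = 0.000277, adjusted p = 0.563 with an estimated correlation). Upper-quartile scaling left 5 of the 23 lower (median log2 change -0.12 against -0.26), and library totals only left 7 lower (median -0.15). Cpsf3, the polyadenylation endonuclease gene related to Ints11, fell from 125 ± 10.96 to 85.95 ± 1.36 CPM, and the cleavage factor genes Nudt21 (log2 change -0.56) and Cstf2 (-0.58) and the exonuclease gene Xrn2 (-0.52) fell as well. Integrator subunits with the neutrophil covariate were 1 higher and 0 lower (median -0.05 against -0.23). Ints7 (log2 change from -0.51 to -0.34), Nabp1 (from 1.64 to 0.88), Cpsf3 (from -0.53 to -0.36), Nudt21 (from -0.56 to -0.37), Cstf2 (from -0.58 to -0.33) and Xrn2 (from -0.52 to -0.31) no longer passed.

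Only 3 of the 5 genes that matched the name pattern for small nuclear RNAs could be tested, too few for camera. Rnu11, the U11 RNA of the minor spliceosome, rose 3.96-fold from 9.29 ± 3.46 to 36.7 ± 6.04 CPM. It was the 1 member of 3 that passed (1 adjusted over the list alone). Rnu12 had a log2 change of 0.61 (adjusted p = 0.0984) and Rnu73b, annotated as a small nucleolar RNA, one of -0.57 (adjusted p = 0.1395), in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Rnu12 passed without WT_341 (log2 change 0.93), with DESeq2 (0.61) and with limma-voom with sample quality weights (0.76), and Rnu73b with sex as a covariate (-0.73). These RNAs lack long poly(A) tails and the libraries were made with a messenger RNA kit, so their counts do not measure the amount of mature small nuclear RNA.

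Genes of haematopoietic stem cells rose in 18 of 32 cases with 0 lower over all genes (19 higher and 2 lower adjusted over the list alone; median log2 change 0.81, camera adjusted p = 5.61e-05, adjusted p = 0.535 with an estimated correlation). Angpt1, a ligand of the Tie2 receptor, rose 2.71-fold to 102 ± 17.5 CPM, the transcription factor gene Gata2 2.66-fold to 60.4 ± 12.99 CPM, Meis1 1.62-fold to 37.8 ± 3.27 CPM and Fgd5 2.67-fold to 2.74 ± 0.671 CPM. Megakaryocyte genes rose in 18 of 24 cases with 0 lower (20 and 0 adjusted over the list alone), with a median of 1.43 (camera adjusted p = 1.27e-07, adjusted p = 0.482 with an estimated correlation). Itga2b, which encodes the integrin CD41, rose 2.25-fold to 66.8 ± 3.39 CPM, and the platelet glycoprotein genes Gp1bb and Gp9 rose 4.88-fold and 3.64-fold. Of 24 mast cell, basophil and eosinophil genes, 17 rose and 2 fell (20 and 2 adjusted over the list alone; camera adjusted p = 7.82e-06, adjusted p = 0.482 with an estimated correlation). Eosinophil peroxidase, Epx, rose 2.55-fold to 866 ± 120 CPM and the eosinophil ribonuclease genes Ear1 and Ear2, close paralogs, rose 2.95-fold and 3.24-fold, whereas the cytokine receptor gene Il6st fell (log2 change -1.12). Kit itself, the gene of the sorted marker and a member of the stem cell list, was at 211 ± 11.5 CPM in WT and 228 ± 9.28 CPM in KO libraries and did not pass (log2 change 0.11, adjusted p = 0.269, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Mast cell, basophil and eosinophil genes with the neutrophil covariate were 6 higher and 1 lower (median 0.60 against 0.98). The stem cell genes Gata2 (log2 change from 1.41 to 1.34), Meis1 (from 0.70 to 0.60) and Fgd5 (from 1.41 to 1.14) no longer passed.

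Granulocyte-macrophage progenitor and granule genes fell in 13 of 25 cases, with 1 higher (13 and 1 adjusted over the list alone; median log2 change -0.40, camera adjusted p = 0.000671, adjusted p = 0.563 with an estimated correlation). Myeloperoxidase, Mpo, fell from 12317 ± 1902 to 5474 ± 412 CPM, Ms4a3 from 870 ± 167 to 352 ± 44.6 CPM, Plac8 from 1851 ± 349 to 898 ± 59.5 CPM and the glutathione transferase gene Gstm1 from 372 ± 37.1 to 140 ± 25.3 CPM. Monocyte and dendritic cell genes moved both ways, with 8 lower and 3 higher of 24 (8 and 3 adjusted over the list alone; camera adjusted p = 0.227, and 0.0448 without KO_345). Besides Ccr2, the monocyte transcription factor gene Irf8 fell from 99.5 ± 20.3 to 40.3 ± 4.21 CPM, Ms4a6c from 98.6 ± 4.48 to 41.5 ± 7.82 CPM and Ly86 from 20.7 ± 3.69 to 6.52 ± 2.04 CPM. With the neutrophil covariate the first list was 0 higher and 6 lower (median -0.45 against -0.40) and the second 1 higher and 4 lower (median 0.14 against -0.17). Ly86 (log2 change from -1.67 to -1.31) no longer passed.

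Of 30 erythroid genes 6 fell and 0 rose (6 and 0 adjusted over the list alone; camera adjusted p = 0.0897), among them the haem synthesis genes Fech (log2 change -0.86) and Cpox (-0.74) and the transferrin receptor gene Tfrc (-0.58). The Cpox call was lost without KO_339 or KO_340 and the Tfrc call without KO_339. The erythroid list stood higher in WT_341 than in the other WT libraries (mean log2 CPM 4.62 against 3.09 and 3.26), and without WT_341 its counts were 8 higher and 6 lower, with the median going from -0.66 to 0.16. Its camera result ranged over the left-out libraries from an adjusted p of 0.00654 without WT_343 to 0.520 without WT_341, and camera called the list lower without WT_343, WT_344 (0.0155) or KO_345 (0.0434). The adult globin genes are listed at 0 in all libraries. Lymphoid progenitor and B cell genes rose in 4 of 23 cases with 0 lower (0 and 0 adjusted over the list alone; camera adjusted p = 0.0379, adjusted p = 0.669 with an estimated correlation). Lck, Ly6d, Notch1 and Ccr9 were these 4, with log2 changes of 0.67, 0.84, 0.57 and 0.72, each lost without KO_339 or KO_345. Lck, Ly6d and Ccr9 were also lost without WT_343 or WT_344, Ly6d and Notch1 without KO_340 and Ccr9 without WT_341. Without WT_341 the count was 13 of 23, and the camera call was lost without WT_343 (adjusted p = 0.245), WT_344 (0.0568), KO_339 (0.0801) or KO_345 (0.0742). In the fit with the neutrophil covariate erythroid genes were 0 higher and 6 lower (median -1.02 against -0.66) and lymphoid genes 0 higher and 0 lower (median -0.66 against 0.57). Cpox (log2 change from -0.74 to -0.92), Tfrc (from -0.58 to -0.24), Lck (from 0.67 to 0.51), Ly6d (from 0.84 to 0.30), Notch1 (from 0.57 to 0.21) and Ccr9 (from 0.72 to 1.13) no longer passed. Notch1 was also lost with no low-count filter and with sex as a covariate.

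Markers of mature neutrophils were higher in KO libraries and varied within WT. The list took 3.97, 1.22 and 2.25% of all counts in WT_341, WT_343 and WT_344, and 6.39, 5.02 and 5.03% in KO_339, KO_340 and KO_345 (2.48 ± 1.39% against 5.48 ± 0.789%, n = 3 each, exact two-sided permutation test, p = 0.10, the smallest possible). Of 24 members 9 rose and 0 fell (9 and 0 adjusted over the list alone; camera adjusted p = 5.61e-05, adjusted p = 0.604 with an estimated correlation), and without WT_341 20 rose. The gelatinase gene Mmp9 rose 2.33-fold to 279 ± 23.1 CPM, Pglyrp1 1.801-fold, Stfa2l1 2.12-fold and the decoy receptor gene Il1r2 1.48-fold, each lost without KO_339 or KO_345. Mmp9, Pglyrp1 and Stfa2l1 were also lost without KO_340 or WT_344, and Stfa2l1 without WT_343. Of 21 T and NK cell genes 9 rose and 1 fell (11 and 1 adjusted over the list alone; camera adjusted p = 0.00130, adjusted p = 0.563 with an estimated correlation). Cd247, Cd3g and Eomes rose 2.47-fold, 4.49-fold and 4.41-fold to levels of 1.297, 0.8202 and 1.01 CPM, and Nkg7, which myeloid progenitors also express, fell (log2 change -0.49). The neutrophil covariate, made from the first list, left it at 0 higher and 0 lower (median -0.07 against 0.95). Mmp9 (log2 change from 1.22 to 0.28), Pglyrp1 (from 0.85 to 0.13), Stfa2l1 (from 1.08 to 0.46), Il1r2 (from 0.57 to 0.30), Cd3g (from 2.17 to 2.41), Eomes (from 2.14 to 2.72) and Nkg7 (from -0.49 to -0.36) no longer passed. Mmp9 and Pglyrp1 were also lost with no low-count filter.

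Stromal and endothelial genes rose in 6 of 24 cases with 0 lower (6 and 0 adjusted over the list alone; camera adjusted p = 0.00738, adjusted p = 0.626 with an estimated correlation). Next to Col1a1 these included the pericyte receptor gene Pdgfrb, at 17.7 ± 2.59 CPM in KO libraries, and Lum and Bglap at 0.229 and 0.205 CPM. The KO libraries differed: the mean log2 CPM of the list was 1.4 in KO_339 and 1.48 in KO_345 but 0.0944 in KO_340. It was -0.4445, 0.446 and 0.188 in WT_341, WT_343 and WT_344. The camera call was lost without WT_341 (adjusted p = 0.0920) or KO_345 (0.0634), the Pdgfrb call without WT_344, KO_339 or KO_340, and the Bglap call without WT_343, WT_344 or KO_339. Of 23 macrophage genes 2 rose and 0 fell (1 and 0 adjusted over the list alone). Their median log2 change was -0.04 and their mean -0.16, while the direction of the camera test was higher (adjusted p = 0.703), and the median was 0.11 with upper-quartile scaling and 0.08 with library totals only, 0.62 with sex as a covariate, 1.54 with the mature neutrophil level as a covariate and -0.56 without WT_341. The adhesion molecule gene Vcam1 rose 1.53-fold to 398 ± 23.1 CPM and Cd14 rose 1.32-fold, the second a call lost without WT_343, WT_344, KO_339 or KO_345. Cd163 (log2 change 0.32) and Spic (-1.24) did not pass; Cd163 passed with upper-quartile scaling (0.45) and Spic without WT_341 (-1.73) and with limma-voom with sample quality weights (-1.74). With the neutrophil covariate Col1a1 (log2 change from 3.34 to 2.60), Pdgfrb (from 0.84 to 0.35), Lum (from 3.39 to 1.59), Bglap (from 2.19 to 1.43), Vcam1 (from 0.62 to 0.44) and Cd14 (from 0.40 to 0.19) no longer passed.

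**Figure D2:**
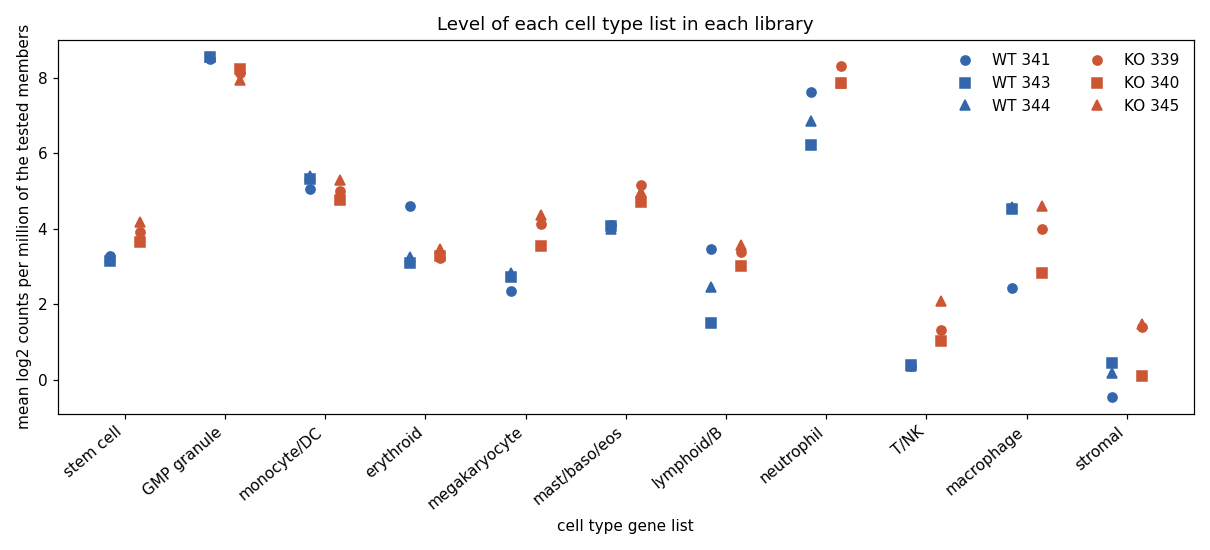
Mean log2 CPM of the tested members of 11 cell type lists, 1 point per library (3 WT, 3 Ints11 KO, each with its own symbol). WT_341 stands apart from WT_343 and WT_344 in the erythroid list (4.62 against 3.09 and 3.26) and the macrophage list (2.42 against 4.53 and 4.57).

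Immediate early genes rose in 14 of 33 cases with 0 lower (14 and 0 adjusted over the list alone; median log2 change 0.90, camera adjusted p = 1.83e-05, adjusted p = 0.482 with an estimated correlation). The phosphatase gene Dusp6 rose 2.09-fold to 187 ± 23.5 CPM, Ier5 2.53-fold to 115 ± 17 CPM, Ier3 1.901-fold to 46.05 ± 1.98 CPM and Arc 9.86-fold to 1.18 ± 0.139 CPM. Of 26 NF-kB and inflammatory genes 4 rose and 0 fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.0677). They were the cytokine gene Tnf (2.35-fold to 93.9 ± 16.9 CPM), the feedback inhibitors Nfkbia (1.42-fold) and Tnfaip3 (1.46-fold), and Birc3 (log2 change 0.26). The Birc3 call was lost without WT_343, WT_344 or any KO library and the Tnfaip3 call without WT_344, and camera called the list without WT_343 (adjusted p = 0.0474) or KO_340 (0.0211). Without WT_341 the list had 8 members higher and 1 lower, and with sex as a covariate 9 higher and 0 lower. Immediate early genes with the neutrophil covariate were 5 higher and 0 lower (median 0.49 against 0.90) and the NF-kB list 0 higher and 1 lower (median 0.48 against 0.29). Tnf (log2 change from 1.23 to 0.59), Nfkbia (from 0.51 to 0.63), Tnfaip3 (from 0.55 to 0.67) and Birc3 (from 0.26 to 0.21) no longer passed. Birc3 was also lost with no low-count filter.

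Interferon-stimulated genes, a group that poly(I:C) itself induces, fell in 9 of 40 cases with 0 higher (5 lower adjusted over the list alone, camera adjusted p = 0.0814). The count of lower members is near the 21.5% of all tested protein-coding genes that were called lower. Upper-quartile scaling left 3 lower and 1 higher (median log2 change -0.07 against -0.19), and library totals only left 5 lower and 1 higher. Gbp3 fell by 0.94, Oas1g by 0.82, Oas1a by 0.68 and Trim30a by 0.57 on the log2 scale. The mean log2 CPM of that list was 6.41 in WT_341 against 5.71 and 5.54 in the other WT libraries, and without WT_341 11 members rose and 7 fell. Its camera result ranged over the left-out libraries from an adjusted p of 0.00195 without WT_344 to 0.520 without WT_341, with calls of lower also without WT_343 (0.0190) and KO_345 (0.00962), and the calls of Oas1a and Trim30a were lost without KO_339 or KO_340. The neutrophil covariate left the list at 0 higher and 1 lower (median -0.64 against -0.19). Oas1g (log2 change from -0.82 to -0.92), Oas1a (from -0.68 to -0.88) and Trim30a (from -0.57 to -0.81) no longer passed, and Trim30a was also lost with upper-quartile scaling.

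Genes of the unfolded protein and integrated stress responses fell in 12 of 24 cases, with 2 higher (13 and 3 adjusted over the list alone; median log2 change -0.73, camera adjusted p = 0.0116, adjusted p = 0.626 with an estimated correlation). Those with the smallest p-values were chaperones and folding factors of the endoplasmic reticulum: Hspa5, also called BiP, fell from 1554 ± 325 to 774 ± 16.2 CPM, Calr from 2187 ± 557 to 932 ± 38.6 CPM, Pdia4 from 359 ± 87.8 to 122 ± 5.96 CPM and Sdf2l1 from 144 ± 43.1 to 47.1 ± 2.09 CPM. The stress response list stood higher in WT_343 (mean log2 CPM 6.86) than in WT_341 (6.15) and WT_344 (6.14). It was at 5.92, 5.901 and 5.885 in KO_339, KO_340 and KO_345. Without WT_343 camera still called it (adjusted p = 0.0156). Cytosolic ribosomal protein genes fell in 54 of 84 cases, with 1 higher (63 and 1 adjusted over the list alone; median log2 change -0.42, camera adjusted p = 1.83e-09, adjusted p = 0.623 with an estimated correlation). Rpl14 fell from 703 ± 112 to 436 ± 16.3 CPM and Rpl38 from 342 ± 34.4 to 230 ± 4.15 CPM, and the paralogs Rpl22l1 (log2 change -0.72) and Rpl7l1 (-0.69) also fell. The whole list took 4.82 ± 0.588% of counts in WT and 3.81 ± 0.134% in KO libraries (n = 3 each, exact two-sided permutation test, p = 0.10, the smallest possible). Upper-quartile scaling left 36 of the 84 lower and the median at -0.28. Stress response genes with the neutrophil covariate were 1 higher and 4 lower (median -0.13 against -0.73). Rpl14 (log2 change from -0.69 to -0.39), Rpl38 (from -0.57 to -0.39), Rpl22l1 (from -0.72 to -0.66) and Rpl7l1 (from -0.69 to -0.41) no longer passed.

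**Figure D3:**
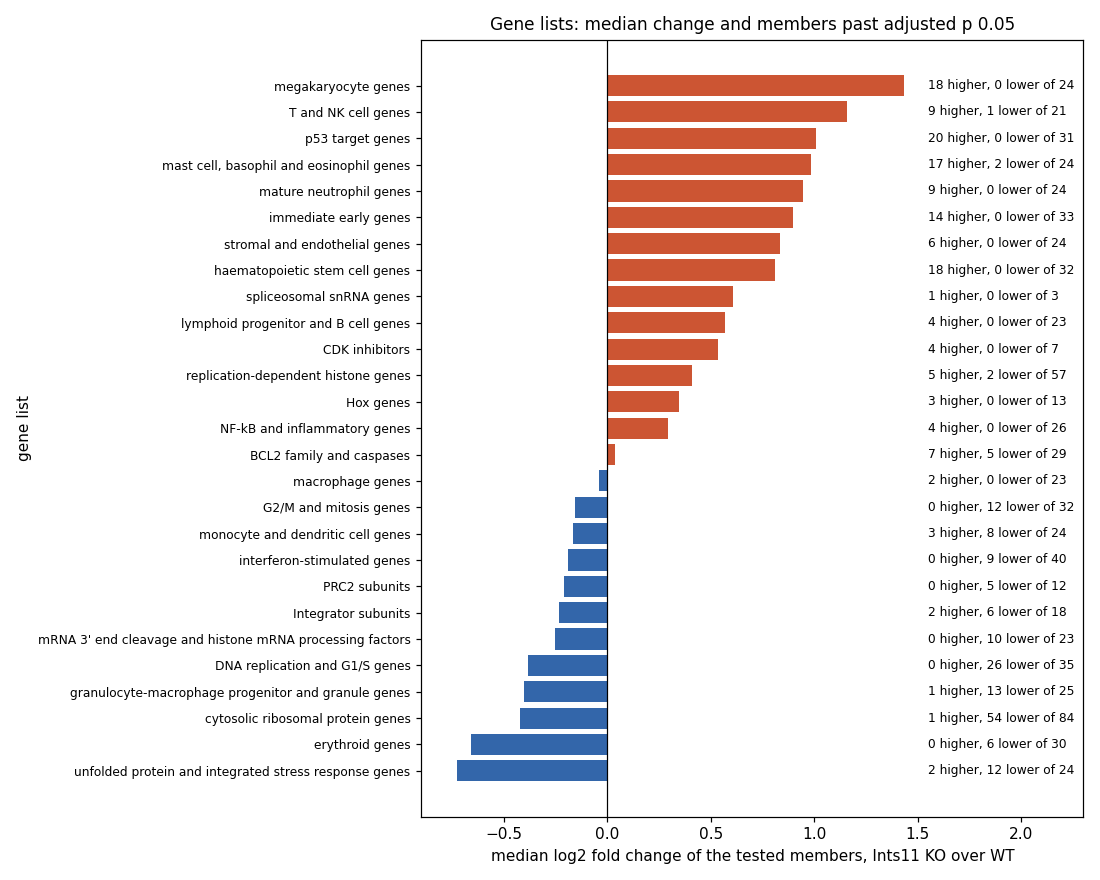
Median log2 fold change (Ints11 KO over WT) of the tested members of each of 27 gene lists, with the number of members past an adjusted p of 0.05 in each direction printed beside each bar. Megakaryocyte genes have the highest median (1.43) and unfolded protein and integrated stress response genes the lowest (-0.73).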

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

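The mature neutrophil covariate was chosen after the data were seen, and all other alternatives were set before. Under 20 alternatives 144 genes other than Ints11 gave 2873 comparisons (121 genes by the rule for named genes, 23 from lists chosen after the data were seen). Of these comparisons 2665 kept their side of the threshold, 194 no longer passed, 14 newly passed and 0 reversed. A change of direction was counted as reversed only where the gene passed in either fit. Genes that passed in neither fit could change direction. With the covariate the log2 changes of Spic (from -1.24 to 1.16), Rnu12 (from 0.61 to -0.18) and Slfn2 (from 0.57 to -0.02) did so. In all, 72 named genes were lost with the covariate and 29, 20 and 21 without KO_339, KO_340 and KO_345. Groups of 2 libraries leave fewer degrees of freedom, and for the other changes below the cause was not tested. In simulated counts the test recovered 6 of 49 genes changed 1.5-fold, but it made only 72 calls there against 5659 in the data. Adjustment over genes is stricter with few calls, so that rate need not hold here. No paired analysis was possible because the labels share no replicate numbers.

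Counts of changed genes were 1931 lower with upper-quartile factors, 842 at least 2-fold with the filter of at least 1 CPM in 3 libraries, and 4030 higher in limma-voom with sample quality weights. With the covariate they were 876 changed, 328 higher, 548 lower and, rounded, 3.4e+02 at least 2-fold, and the Ints11 log2 change was -0.22 (adjusted p = 0.298, range 0.00127 to 0.298). Without single libraries the lowest and highest counts were 2302 and 7879 changed, 1039 and 3573 higher, 1263 and 4306 lower, and 848 and 2236 at least 2-fold. Lists called were 16 to 20, and Ints11 had log2 changes from -0.50 to -0.33.

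Values for lists are camera adjusted p-values. With upper-quartile factors PRC2 subunits, Hox genes and G2/M genes had 0.0589 each and lymphoid genes 0.103, all lost, and interferon-stimulated genes (0.0377) and erythroid genes (0.0252) were gained. With library totals only Hox (0.0519) and lymphoid genes (0.0802) were lost, and interferon-stimulated (0.0495) and erythroid genes (0.0362) gained. With no low-count filter lymphoid genes (0.0515) were lost, and Integrator subunits (0.0337), interferon-stimulated (0.0251) and erythroid genes (0.0335) gained. With at least 1 CPM in 3 libraries PRC2 (0.116) and G2/M genes (0.0925) were lost and NF-kB genes (0.013) gained. On DESeq2's scale Hox (0.0558) and lymphoid genes (0.116) were lost, and monocyte (0.0438) and erythroid genes (0.048) gained. With limma-voom Hox genes (0.0836) were lost and NF-kB genes (0.0377) gained, and with quality weights Hox (0.144) and histone genes (0.188) were lost. With sex as a covariate lymphoid genes (0.0663) were lost, and interferon-stimulated (0.0261), NF-kB (0.00391) and erythroid genes (0.0124) gained. Without members shared between lists lymphoid genes (0.0553) were lost.

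With the neutrophil covariate PRC2 (0.0816), inhibitors of cyclin-dependent kinases (0.228), histones (0.0926) and stress response genes (0.155) were lost, and interferon-stimulated (4.15e-07), NF-kB (0.0270), erythroid (9.32e-08) and macrophage genes (0.00932) gained. Lymphoid genes reversed to lower (0.0235), and so did the neutrophil list (0.477), which the covariate itself removes. With an estimated correlation 0 lists were called: 0.0718 for p53 targets, 0.482 for Hox, cyclin-dependent kinase inhibitor, replication, immediate early, megakaryocyte and mast cell lists, 0.535 for stem cell, 0.563 for 3' end, PRC2, granulocyte-macrophage and T and NK cell, 0.604 for neutrophil, 0.623 for ribosomal protein, 0.626 for G2/M, stress response and stromal, 0.669 for lymphoid and 0.704 for histone genes. By fry histone (0.317), stress response (0.112), ribosomal protein (0.0655), lymphoid (0.220), neutrophil (0.0734), T and NK cell (0.0690) and stromal genes (0.180) were lost, and the BCL2 family and caspases (0.0344) gained.

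Over the 6 fits without 1 library, lists that crossed the threshold ranged from 0.0156 to 0.0920 (Hox), 1.03e-06 to 0.113 (histones), 0.00195 to 0.520 (interferon-stimulated), 0.0211 to 0.182 (NF-kB), 0.0448 to 0.397 (monocyte and dendritic cell), 0.00654 to 0.520 (erythroid), 0.00173 to 0.245 (lymphoid) and 6.40e-06 to 0.0920 (stromal).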

Other observations

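All lists and tests in this part were chosen after the data were seen, except the test of reads running on from upstream genes and the counts over other splits of the libraries. Many single genes of protein synthesis beyond the ribosomal proteins were called lower in KO libraries. The gene lists in this paragraph were picked from the same data on which they are tested. Their camera p-values therefore cannot decide whether a list as a whole differs, and no conclusion is drawn from them. The lists were not matched on expression level, and their member counts under other scalings are not given. Of the aminoacyl-tRNA synthetase genes, which charge transfer RNAs, 20 of 20 fell (camera adjusted p = 4.30e-07, adjusted p = 0.426 with an estimated correlation), with Iars from 195 ± 45.4 to 102 ± 11.3 CPM and Lars from 203 ± 49.3 to 115 ± 1.32 CPM. Ribosome biogenesis genes fell in 24 of 32 cases (camera adjusted p = 4.30e-07, adjusted p = 0.426 with an estimated correlation), among them Nop56 (log2 change -0.92) and the nucleophosmin gene Npm1 (-0.89). Mitochondrial ribosomal protein genes fell in 48 of 77 cases (camera adjusted p = 2.21e-11, adjusted p = 0.426 with an estimated correlation), with Mrps35 at -1.05 and Mrps24 at -0.99. Sterol biosynthesis genes fell in 15 of 24 cases (camera adjusted p = 4.35e-06, adjusted p = 0.278 with an estimated correlation), with Fdps, the farnesyl diphosphate synthase gene, at -1.37, and glycolysis genes in 7 of 15 cases (camera adjusted p = 0.00271, adjusted p = 0.426 with an estimated correlation), with Pdk1 from 88.7 ± 15.7 to 33.7 ± 3.51 CPM. None of these lists had a member higher. With the mature neutrophil level as a covariate the log2 changes of Iars (from -0.94 to -0.41), Lars (from -0.82 to -0.39) and Npm1 (from -0.89 to -0.37) no longer passed, and those of Nop56 (-0.51), Mrps35 (-0.75), Mrps24 (-0.66), Fdps (-1.17) and Pdk1 (-0.96) passed. Slfn14 was the 1 Schlafen gene of 8 that passed (camera adjusted p = 0.423, adjusted p = 0.652 with an estimated correlation). Slfn2 (log2 change 0.57) did not pass, and passed with DESeq2 (0.58), limma-voom with sample quality weights (0.57), without WT_341 (0.77) and without WT_343 (0.35).

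Long non-coding genes were called higher more often than lower, 142 (20.7%) against 25 (3.64%) of 687 tested, while of 14279 protein-coding genes 2297 (16.1%) were higher and 3076 (21.5%) lower. The odds ratio of being higher was 1.36 (95% interval 1.12 to 1.65, Fisher's exact test, p = 0.00212, across genes, which are not independent). The comparison was not matched on expression level, so it cannot tell the class of a gene apart from its level. The antisense gene 2900060B14Rik (chromosome 1, 118458652 to 118459267, reverse strand) rose 20.9-fold from 3.31 ± 0.808 to 68.95 ± 7.03 CPM and overlaps the small nuclear RNA gene Gm22710. It lies inside Clasp1 on the other strand, which encodes a microtubule-binding protein and fell from 177 ± 6.56 to 75.3 ± 5.38 CPM. The strand setting of the counting is not given in the sources used here, so which of this pair a read came from is uncertain.

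More genes were detected in KO libraries, 18594.3 ± 109 against 17723.7 ± 114 in WT (n = 3 each, exact two-sided permutation test, p = 0.10, the smallest possible). Sequencing depth does not account for it: with every library thinned to the smallest total the difference was 959.7 genes, against a larger group SD of 107.3. Genomic DNA would spread its reads over the 1122 olfactory receptor genes, yet 45.3 of them gained a read where an even spread of all the extra reads gives 741.9. In KO libraries 61.5% of the olfactory receptor counts lay in the 10 most counted of these genes. This argues against genomic DNA as the source of all those reads, while a smaller contribution of DNA was not tested and stays open. Reads running on from expressed genes upstream may add to it, since of 8940 genes with a known position and under 0.1 CPM in WT the 735 raised in all KO libraries had an expressed gene within 20 kb upstream on the same strand more often than the rest (odds ratio 3.85, 95% interval 3.12 to 4.74), but the odds ratio for a downstream neighbour was 3.35 and upstream-only against downstream-only neighbours gave 1.15 (Fisher's exact test, p = 0.393). Run-on transcription and a general rise of lowly expressed genes in active regions cannot be told apart by position alone, and an effect of genotype stays open.

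Mean levels of the mature neutrophil list and of the T and NK cell list were higher in every KO library of a Kit-positive sort than in every WT library. The stromal list was higher only on average: KO_340 (mean log2 CPM 0.0944) lay below WT_343 (0.446) and WT_344 (0.188). The larger group SD of the stromal list was 0.78. A lower share of the sorted cells would raise all other cell types alike, and mean log2 levels were 1.12 (neutrophil), 1.1 (T and NK cell) and 0.93 (stromal) higher in KO libraries against -0.04 for the macrophage list, whose level varied by an SD of up to 1.23 within a genotype. The neutrophil level less the macrophage level differed by 1.15 between the genotypes, within the larger group SD of 1.87 (n = 3 each, exact two-sided permutation test, p = 0.40, smallest possible p = 0.10). A lower share of the sorted cells, neutrophil RNA carried into the sort and a change of the Kit-positive cells themselves therefore cannot be told apart. With the neutrophil level as a covariate 876 of the tested genes passed, against 5659 without it, and the p53 targets that passed numbered 19 of 31.

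Tex14 and Rdm1 prompted a look at genes on the same strand as U1, U2, U5, U7, U11 and U12 copies. Of 15 tested neighbours 4 rose at least 2-fold, Tex14, Rdm1, Arl4d (log2 change 2.63) and Grcc10 (1.45), against 8.63% of all tested genes. Low expression of these genes was not excluded as an explanation. Of 10000 random lists matched on expression, a share of 0.0268 held as many. That share is under 0.05, but it counts the 2 genes that prompted the test. Without these 2 genes the share was 0.357. The U7 gene Rnu7 overlaps an annotated exon of Grcc10, and whether its reads were counted for Grcc10 was not tested. Nearness to any small nuclear RNA copy also stays open, as 5 of 40 neighbours of U6 copies rose at least 2-fold (odds ratio 2.5, 95% interval 0.42 to 14.05, Fisher's exact test, p = 0.236), and on the opposite strand 2 of 8 neighbours of the 6 classes and 9 of 38 of U6 copies did (difference between strands not tested). Transcription running past unprocessed small nuclear RNA ends in Ints11 KO cells is a hypothesis that these 15 genes are too few to decide, so neither explanation can be told apart from it. Only copies of the 6 classes and of U6 were looked at. The gene 2900060B14Rik overlaps Gm22710, which matched none of these classes, on its own strand and is therefore not among the 15.

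The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. Every split but the real one puts both genotypes in each group, so a difference between the genotypes adds to the spread within its groups. Low counts in the other splits therefore do not separate an effect of genotype from any other difference that follows the groups. The real split was the 1 with the most genes changed (5659, highest other 5), higher (2520, highest other 4), lower (3139, highest other 4) and changed at least 2-fold (1536, highest other 5). The direction of the other splits is arbitrary, so for higher and lower the larger of their 2 directions was taken. The split by sex gave 5 changed genes, 1 higher and 4 lower. It also mixes the genotypes, so this count does not measure the effect of sex. Of the 10 splits, 2 called 19 or more gene lists by camera, the real one with 19 and another with 22.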
